A study of Homo sapiens with 8 samples.

How the data were processed

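Total RNA of H1 human embryonic stem cells was extracted with Trizol, depleted of ribosomal RNA with Ribo-Zero and made into ScriptSeq v2 libraries, per the labels. Spike-in RNA was added, per the labels, but the tables analysed here hold 0 spike-in entries. The 8 libraries cover 2 hairpins (shEXOSC3 and the non-silencing shNS), doxycycline or none, and days 5 and 7, with 1 library per group; groups were taken from the sample titles. Per the submitters' processing notes, CASAVA 1.8, TopHat and Cufflinks were used with the human build hg19 (GRCh37). The versions of TopHat and Cufflinks, the annotation release, the normalization option and the use of strand in counting are not given in the sources used here. ScriptSeq makes directional libraries, but without a stated counting strand, overlapping and antisense genes cannot be separated.

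The data used were 4 tables, each with the untreated and the doxycycline library of 1 line on 1 day. Per the file headers, the deposited values are FPKM in the layout of Cuffdiff, with 1 entry per RefSeq transcript and 49235 transcripts per table. Each table also holds the authors' deposited p-value and q-value for a test of 1 library against 1 library. That test has no replicates, and in the authors' deposited tables no transcript (0) was marked significant, with smallest q of 0.0926 and 0.105 in shEXOSC3 and 0.0683 and 0.0732 in shNS on days 5 and 7. FPKM of separately made tables can differ in scale, so ratios were formed only within a table, except in 1 alternative. Transcript FPKM also depend on how shared reads are divided among the transcripts of a gene, which can move a value without any difference in the gene's total.

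Accessions were matched to gene symbols through a reference table of RefSeq accessions, used for names only since it belongs to a later assembly; 48143 of 49235 transcripts (97.8%) had a symbol and 1092 did not. These gave 25554 symbols, of which 9669 had several accessions. Coordinates are those of the deposited tables, on hg19. A gene was represented by its transcript with the highest mean FPKM over the 8 libraries. The 164 transcripts with a failed or too deep estimate in any table were left out before that choice. Another transcript could then stand for the gene. For values summed over transcripts, genes with such a transcript were left out whole. Genes with a mean below 1 FPKM were also left out, which left 12965 genes by the transcript with the highest mean. The log2 ratio was log2((FPKM + 1)/(FPKM + 1)) of doxycycline over no doxycycline, a scale that understates differences of low genes. The adjusted log2 difference is the ratio in shEXOSC3 minus that in shNS of the same day. With 1 library per group a gene passed by size alone, at an absolute log2 value of at least 1, or on both days in the same direction for the adjusted difference; the same rule was applied to the ratio of each line alone, which varies less than a difference of 2 ratios. Overlaps between days were set beside those of independent lists. The days share no library.

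The day-averaged effect was tested with limma 3.58.1 in R 4.3.3, on the 4 ratios, shEXOSC3 against shNS, with a trend on expression, 2 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. Days are time points and not replicates, so this test measures a difference against the spread between days. Agreement between days was given as Pearson and Spearman correlation across genes. Gene lists were exosome subunits, exosome cofactors, pluripotency, mesendoderm and primitive streak, definitive endoderm, mesoderm, neuroectoderm, trophectoderm and amnion, fibroblast and stromal genes, snoRNA hosts, p53 targets, the integrated stress and unfolded protein response, interferon response, ribosome biogenesis, cell cycle, nodal and TGF-beta targets, WNT targets, retinoic acid targets and HOX genes, and mitochondrial translation with respiratory complex I. Classes by symbol were C/D box and H/ACA box snoRNAs, Cajal body RNAs, snRNAs, microRNA genes and hosts, LINC and antisense RNAs, replication-dependent histones, ribosomal proteins and ZNF genes. The mitochondrial genome and spike-in classes had 0 measured members and the class of RN7, RNase P and MRP RNAs had 2, too few for a median. For each list the median was given with its percentile among 10000 random lists of the same size, drawn from the same 10 bins of expression; it describes these libraries and is not a test across replicates.

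Named genes were EXOSC3 and the measured exosome subunits, the 12 highest and 12 lowest genes past the adjusted rule on both days, up to 2 members at each end of every list, POU5F1, NANOG, SOX2 and FOXH1, the 5 highest and 5 lowest by the difference between days, and the 5 largest in shNS on both days. The ranked parts left out short RNAs, loci under 300 bp and entries without a single symbol. Of the genes this rule names, 1 is not reported here. Groups, designs, lists, this rule and most alternatives were set before the data were examined. Alternatives set then were pseudocounts of 0.1 and 5 FPKM, centring of ratios, no minimum or a minimum of 5 FPKM, only successfully tested transcripts, loci of at least 300 bp, a fold of 1.5, shEXOSC3 without subtraction, doxycycline libraries compared across tables, limma without trend or with day as a block, and each ratio left out in turn. FPKM summed over the transcripts of a gene (13387 genes) and genes with 1 transcript only (6784 genes) were added after the data were seen, because single transcripts of many genes moved while the sum did not.

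Depth was read from the spacing of values under 0.5 FPKM, which shows the value of 1 read in each library of a table relative to the other, and not the total. The calculations were tested on simulated data with known differences in 200 genes. For both lines the simulated ratios were shNS ratios of the same day, shuffled among genes in the same bin of expression. Such data do not keep the spread of each gene. Nor do they keep the larger spread of shEXOSC3 on day 5, with an SD across genes of 0.708 against 0.571 in shNS. On dominant transcripts the size rule recovered 79% of 100 genes moved by 1.5 and 94% of 100 moved by 3 on the log2 scale, with 71 of 12765 unmoved genes passing, and limma recovered 0% of either. On summed values the size rule recovered 87% and 98%, with 12 of 13187 unmoved genes passing, and limma 15% and 82%, with 2. Lists were simulated for day 5. Of 200 simulated lists of 25 unmoved genes, 5.5% lay outside the central 95% of random lists. Of lists moved by 0.3, 98% lay above it. Members were drawn at random and the shuffle removes correlation between genes, so the first share was nearly fixed in advance. Lists of genes that move together can lie outside more often. In the control shNS, pluripotency genes lay at percentile 0 on day 5 and p53 targets at percentile 0 on day 7. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for all other steps. The concentration of doxycycline in the labels was not used.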

Results

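Total RNA of H1, an established human embryonic stem cell line, was sequenced in 8 libraries. The cells carried a doxycycline-inducible short hairpin RNA against EXOSC3 (shEXOSC3) or a non-silencing hairpin (shNS). EXOSC3 is a core subunit of the RNA exosome, the complex that trims and degrades many classes of nuclear and cytoplasmic RNA. Each line was measured with and without doxycycline after 5 and 7 days, which gave 8 groups of 1 library each. The title of the series names the exosome in the differentiation of these cells as its subject. Values were FPKM of 49235 RefSeq transcripts, in 4 separately made tables that each hold the doxycycline and the untreated library of 1 line on 1 day. Summed over transcripts, FPKM ran from 675742 to 785419 per library, and 17192 to 17932 transcripts reached 1 FPKM. Read counts and total depth are unknown. From the spacing of low values, the doxycycline library held 1.01 and 0.922 times the depth of its untreated partner in shEXOSC3 on days 5 and 7, and 1.59 and 1.33 times in shNS. The 3 most abundant transcripts took 23.8% to 27.6% of all FPKM on day 5 and 6.21% to 7.16% on day 7, so the days also differed in library composition. No group had a replicate, so differences have no replicate check and no p-value was computed between single libraries.

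EXOSC3 itself was examined first, since it shows whether the labelled libraries carry the knockdown. The EXOSC3 transcript NM_016042 (hg19, chromosome 9, 37779711 to 37785089) fell with doxycycline in shEXOSC3 from 24.5 to 7.54 FPKM on day 5, or 30.7% of the untreated level, and from 25.2 to 9.13 FPKM on day 7, or 36.2%. In shNS it stood at 26.9 and 27.8 FPKM on day 5 and at 27.6 and 27.4 FPKM on day 7. On the log2(FPKM + 1) scale, the doxycycline ratio in shEXOSC3 minus that in shNS, called the adjusted log2 difference from here on, was -1.63 on day 5 and -1.37 on day 7. A second EXOSC3 transcript, NM_001002269, was listed at 0.627 and 3.77 FPKM on day 5 and at 0 and 3.22 FPKM on day 7 in shEXOSC3. In shNS it was listed at 0.415 and 0 FPKM on day 5 and at 2.68 and 0 FPKM on day 7. With both EXOSC3 transcripts summed, the shEXOSC3 level with doxycycline was 45.0% and 48.9% of the untreated level. The summed shNS level was 102% and 90.6%. The adjusted log2 differences of the sum were -1.11 and -0.84, the latter short of a 2-fold difference. With the 2 days of a line used as its observations, limma gave EXOSC3 a mean difference of -1.496 (SE 0.138), with an adjusted p of 0.0089 adjusted over the list alone and 0.82 over all genes. In the authors' deposited table, the p of NM_016042 was 0.00025 on day 5 and 0.0004 on day 7, with q of 0.252 and 0.341.

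**Figure D1:**
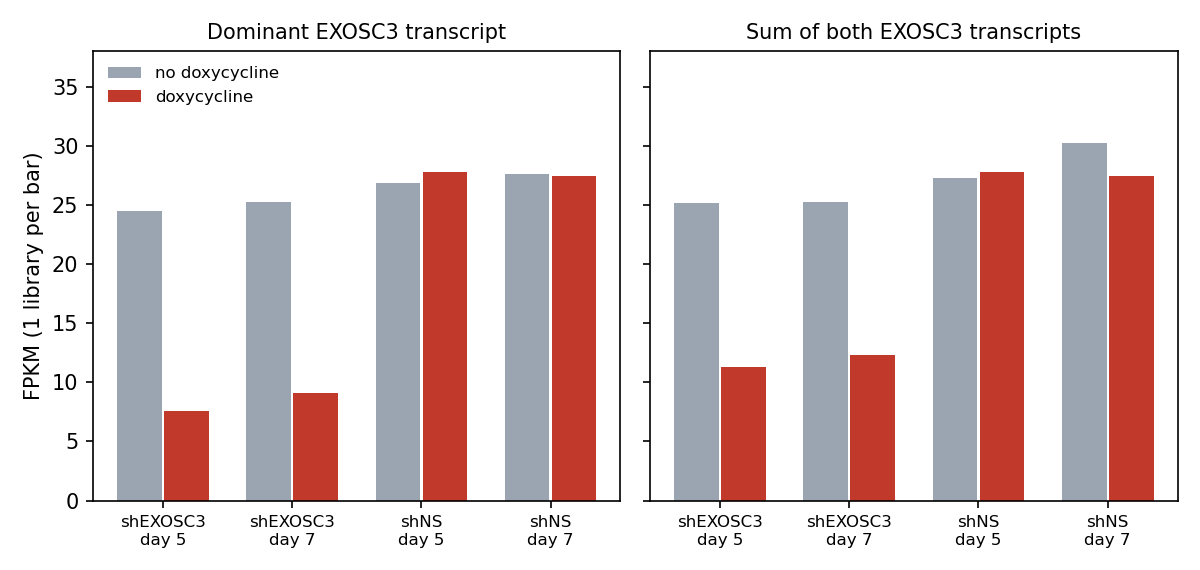
EXOSC3 level in FPKM in the 8 libraries, by line, day and doxycycline, for the dominant transcript NM_016042 (left panel) and the sum of its 2 transcripts (right panel); each bar is 1 library and there are no error bars. The shEXOSC3 libraries with doxycycline stand at 7.54 and 9.13 FPKM on the left, where the other 6 stand at 24.5 to 27.8 FPKM, and at 11.3 and 12.3 FPKM on the right.

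The other subunits of the exosome showed smaller differences. Of the 14 measured members of the list, 2 lay above 0 on both days, 4 below 0 on both days and 8 on different sides, and EXOSC3 was the 1 member that passed the size rule and limma's test adjusted over the list alone; 3 members had an unadjusted p under 0.05. EXOSC6 had adjusted log2 differences of 0.31 and 0.61 on days 5 and 7 and EXOSC9 of 0.45 and 0.63, which for EXOSC9 became -0.37 and -0.26 when its transcripts were summed. MPHOSPH6, a protein bound to the nuclear exosome, had -0.27 and -0.65, EXOSC7 -0.20 and -0.52, and the exosome nuclease DIS3 -0.38 and -0.17. EXOSC1, EXOSC2, EXOSC4, EXOSC5, EXOSC8, the nuclease EXOSC10, DIS3L and the cofactor C1D lay between -0.34 and 0.63. The upper end was C1D on day 7, which had -0.18 on day 5. With transcripts summed, C1D stood at -0.47 and -0.35 and EXOSC2 at -0.16 and -0.25. The list's median was -0.22 on day 5, at percentile 6.35 of 10000 random lists matched on expression, and 0.16 on day 7, at percentile 97.7. Summed over transcripts, the medians were -0.26 on day 5, at percentile 1.24, and -0.14 on day 7, at percentile 7.46. By that sum 1 member lay above 0 on both days, 8 below 0 and 5 on different sides. With doxycycline libraries compared across tables, the day 7 median was -0.057. Among 13 exosome cofactors, which bring RNA to the complex, 6 lay above 0 and 2 below 0 on both days. The zinc finger protein ZFC3H1 had 1.01 and 0.81 and the noncanonical poly(A) polymerase TENT4A 0.80 and 0.40, against -0.73 and -0.04 for ZCCHC7, or -0.34 and -0.08 summed, and -0.33 and 0.02 for SKIC8.

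Doxycycline was compared with no doxycycline within each table to ask how far the knockdown altered the transcriptome. In shEXOSC3, 383 genes were at least 2-fold higher and 306 at least 2-fold lower with doxycycline on day 5, out of 12965 genes represented by their most abundant transcript; on day 7 these were 506 and 450. In shNS, 212 were higher and 191 lower on day 5, and 497 and 405 on day 7. After subtraction of the shNS ratio, 78 genes were at least 2-fold higher and 70 at least 2-fold lower on both days, where independent lists of these lengths would share 27.3 and 23.9. A further 147 genes passed in opposite directions, where 51.3 would be shared. By the ratio of 1 line alone, 41 genes were higher and 36 lower on both days in shEXOSC3, against 36 and 27 in shNS. A difference of 2 ratios varies more than 1 ratio, so the adjusted counts are not set against those of shNS. Among genes at loci of at least 300 bp outside short RNA classes, 15.6% of those with several transcripts passed the adjusted rule on day 7, against 1.799% of those with 1 transcript. Of all 6784 genes with 1 transcript, short RNAs included, 275 were higher and 235 lower on day 7. With FPKM summed over transcripts, an alternative chosen after the data were seen, 41 genes were higher and 25 lower on both days by the adjusted difference. Independent lists of these lengths would share 5.01 and 2.63. In opposite directions 63 summed genes passed, where 7.30 would be shared, so the days also disagreed more often than independent lists would. By the ratio of 1 line alone, 34 summed genes were higher and 18 lower on both days in shEXOSC3, against 19 and 11 in shNS.

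The 12 highest of the genes past the rule on both days were the chromatin and RNA binding protein SAFB (5.02 on day 5 and 3.76 on day 7), the chloride channel family member CLCN3 (1.19 and 5.86), C7orf25 (2.88 and 3.16), SZRD1 (1.03 and 4.96), the Notch regulator NUMB (2.31 and 3.54), SDCBP (1.00 and 4.53), DMAP1 (3.77 and 1.25), ARHGEF1 (3.07 and 1.78), the protein kinase PRKG2 (2.47 and 2.37), cardiac troponin TNNT2 (2.80 and 2.01), the nuclear receptor coactivator NCOA1 (3.31 and 1.45) and the helicase DHX35 (3.41 and 1.25). The 12 lowest were the Hippo pathway transcription factor TEAD2 (-4.13 and -5.93), C21orf91 (-1.68 and -7.89), the spindle checkpoint gene MAD1L1 (-3.20 and -6.12), ING4 (-6.81 and -1.68), PLEKHB2 (-3.55 and -4.17), EIF2B4 (-3.42 and -2.74), UXS1 (-5.09 and -1.04), the protease CTSL (-1.27 and -4.47), DSN1 (-1.39 and -4.04), ZNF180 (-1.20 and -4.19), CYREN (-3.41 and -1.58) and the mitochondrial DNA polymerase POLG (-1.93 and -2.98). All 24 have several RefSeq transcripts, and 0 of the 24 passed the rule once these were summed. SAFB then stood at 0.48 and 0.22, and TEAD2 at -0.09 and -0.12. PLEKHB2 stood at -2.18 and 0.09 and TNNT2 at 0.12 and -1.36, each past a 2-fold difference on 1 day, and the other 22 genes stayed below 2-fold on both days. Most of these values therefore describe single transcripts and not the total RNA of the genes.

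Summing left 11 named genes at loci of at least 300 bp past the rule on both days, 10 higher and 1 lower, and all are given here, chosen after their values were seen. SNHG9, a host of snoRNAs (hg19, chromosome 16, 2014997 to 2015505), went from 9.30 to 23.1 FPKM on day 5 and from 2.92 to 6.34 FPKM on day 7 in shEXOSC3, against 15.6 to 14.7 and 6.89 to 3.10 FPKM in shNS. LINC01139, an intergenic noncoding RNA (hg19, chromosome 1, 238643684 to 238649317), went from 8.26 to 17.1 and from 9.22 to 25.4 FPKM in shEXOSC3, against 9.90 to 8.69 and 7.17 to 7.66 FPKM in shNS. ZNF143-AS1, named as antisense to ZNF143 (hg19, chromosome 11, 9481103 to 9482245), went from 2.70 to 6.46 and from 3.86 to 14.0 FPKM, against 4.43 to 3.94 and 4.30 to 5.19 FPKM in shNS. The antisense genes PCGF3-AS1 and IQCH-AS1 had adjusted log2 differences of 1.42 and 1.03 and of 1.23 and 1.16. The noncoding LOC100129148 had 2.83 and 1.41 and the pseudogene LSP1P5 1.03 and 1.95. The protein-coding genes were RHOBTB1 at 1.43 and 1.60, ZNF789 at 1.47 and 1.03 and DEFB131B at 1.34 and 1.76. On day 7 DEFB131B was lower with doxycycline in shEXOSC3 too, from 11.6 to 5.61 FPKM, and its positive value came from shNS, which went from 5.49 to 0 FPKM. The day 7 values of IQCH-AS1 and SNHG9 also held the larger part from shNS, with log2 ratios of -0.70 and -0.94 there and 0.46 and 0.90 in shEXOSC3. The lower gene was XCL2, at -1.13 and -1.20, whose difference lay in the shNS libraries. The other 55 entries past the rule were short RNAs, loci under 300 bp or transcripts without a single symbol. Whether reads were counted by strand is not given in the sources used here, so antisense genes cannot be told apart from their sense partners by these values alone.

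Gene lists fixed before the data were examined were compared with random lists, beginning with the classes of noncoding RNA that the exosome is known to degrade. Antisense long noncoding RNAs had a median adjusted log2 difference of 0.22 on day 5 and 0.31 on day 7 over 206 genes, both above all 10000 random lists; 95 lay above 0 on both days and 23 below. In shEXOSC3 alone their medians were 0.20 and 0.34, and in shNS -0.04 and 0.06. For 84 intergenic LINC genes the medians were 0.17 and 0.41, at percentiles 99.1 and 100, with 34 above and 8 below 0 on both days. These 2 classes hold low genes: with a pseudocount of 5 FPKM the antisense medians were 0.091 and 0.13 and the LINC medians 0.092 and 0.19, and with no minimum FPKM they were 0.039 and 0.032, and 0 and 0.00058. For 96 H/ACA box snoRNAs, guides of pseudouridylation, the medians were 0.34 and 0.36, above all random lists on both days, with 39 above and 6 below 0, although the day 5 median was -0.67 with doxycycline libraries compared across tables. For 159 C/D box snoRNAs, guides of ribose methylation, the medians were 0.00 and -0.09, at percentiles 100 and 1.89. For 24 Cajal body RNAs they were 0.07 and -0.05, at percentiles 99.7 and 40.5, or -0.39 on day 5 across tables. For 335 microRNA genes they were 0.00 on both days. For 6 spliceosomal snRNA genes they were 0.09 and 1.09, at percentiles 95.4 and 99.9, or -0.85 on day 5 across tables. The random lists matched to short RNAs hold mostly longer genes, for which the mapping of reads differs. On day 5 even a C/D box median of 0.00 lay above all random lists. Percentiles of short RNAs, those of H/ACA box snoRNAs included, are therefore no measure of a raised level by themselves. For 12 microRNA host genes the medians were 0.25 and 0.28, at percentiles 93.7 and 96.97. Among 20 measured snoRNA host genes the medians were 0.15, at percentile 99.6, and 0.03, at percentile 76.0, with -0.019 on day 5 across tables. SNHG9 had 1.31 and 1.85 and SNHG10 0.59 and 1.23, against -0.67 and -0.15 for SNHG6 and -0.41 and -0.04 for ZFAS1. With transcripts summed, SNHG10 passed limma's test adjusted over the list alone (adjusted p 0.0443) and 0 members passed over all genes, with 4 at an unadjusted p under 0.05. Among antisense RNAs, LINC genes and snoRNAs limma called 0 genes over all genes and 0 adjusted over the list alone; at an unadjusted p under 0.05 there were 19 antisense RNAs, 6 LINC genes, 11 H/ACA box and 6 C/D box snoRNAs.

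**Figure D2:**
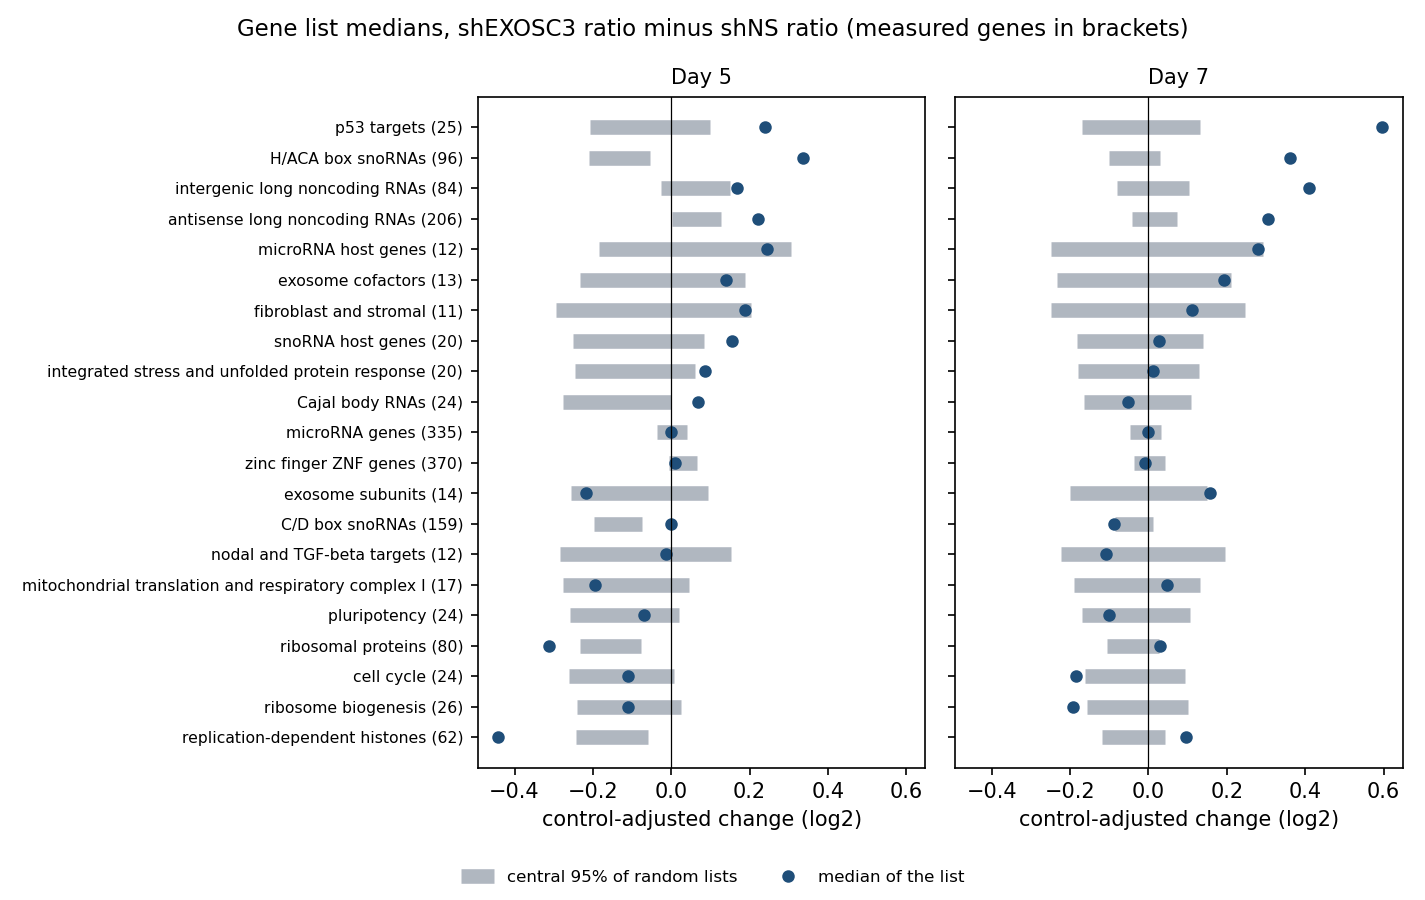
Median adjusted log2 difference (doxycycline ratio in shEXOSC3 minus that in shNS) of the gene lists with over 10 measured genes on day 5 (left) and day 7 (right), named control-adjusted change on the axis, as points, with grey bars for the central 95% of 10000 random lists of the same size matched on expression. Targets of p53, antisense and LINC RNAs and H/ACA box snoRNAs lie above the bars on both days, at medians from 0.17 to 0.60; the H/ACA box median of day 5 was -0.67 with doxycycline libraries compared across tables.

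Targets of p53, the transcription factor that acts in DNA damage and growth arrest, stood higher on both days. All 25 were measured, with a median adjusted log2 difference of 0.24 on day 5, at percentile 99.97, and 0.60 on day 7, at percentile 100; 16 lay above 0 on both days and 0 below. The shEXOSC3 medians were 0.12 and 0.37 and the shNS medians -0.02 and -0.26, so the day 7 difference held both a higher shEXOSC3 and a lower shNS value. The shNS median of day 7 lay below all random lists, at percentile 0, although shNS carries no hairpin against EXOSC3. Of the dominant transcripts, RRM2B had 3.84 and 0.20 and BAX 0.11 and 2.27, against 0.42 and -3.51 for FDXR and -1.85 and 0.60 for GADD45A. Summed over transcripts, 22 of the 25 lay above 0 on both days, with medians of 0.32 and 0.63, and FDXR stood at 0.42 and 0.67, RRM2B at 0.18 and 0.25, BAX at 0.25 and 0.33 and GADD45A at 0.54 and 0.66. By that sum, chosen after the data were seen, limma called 5 genes adjusted over the list alone (adjusted p 0.0482 each) and 0 over all genes, with 13 at an unadjusted p under 0.05; on dominant transcripts the count adjusted over the list alone was 0, with 5 unadjusted. The 5 genes that rose by this test were CDKN1A, the p21 inhibitor of cyclin-dependent kinases, the death receptor FAS, FDXR, ZMAT3 and PHLDA3. CDKN1A (hg19, chromosome 6, 36644237 to 36655116) went from 29.3 to 37.4 FPKM on day 5 and from 20.4 to 33.2 FPKM on day 7 in shEXOSC3, and from 27.0 to 19.6 and from 14.8 to 9.93 FPKM in shNS. Its mean difference was 0.99 (SE 0.156). The dominant transcript of CDKN1A had -0.73 on day 5 and 2.28 on day 7, with opposite signs on the 2 days.

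**Figure D3:**
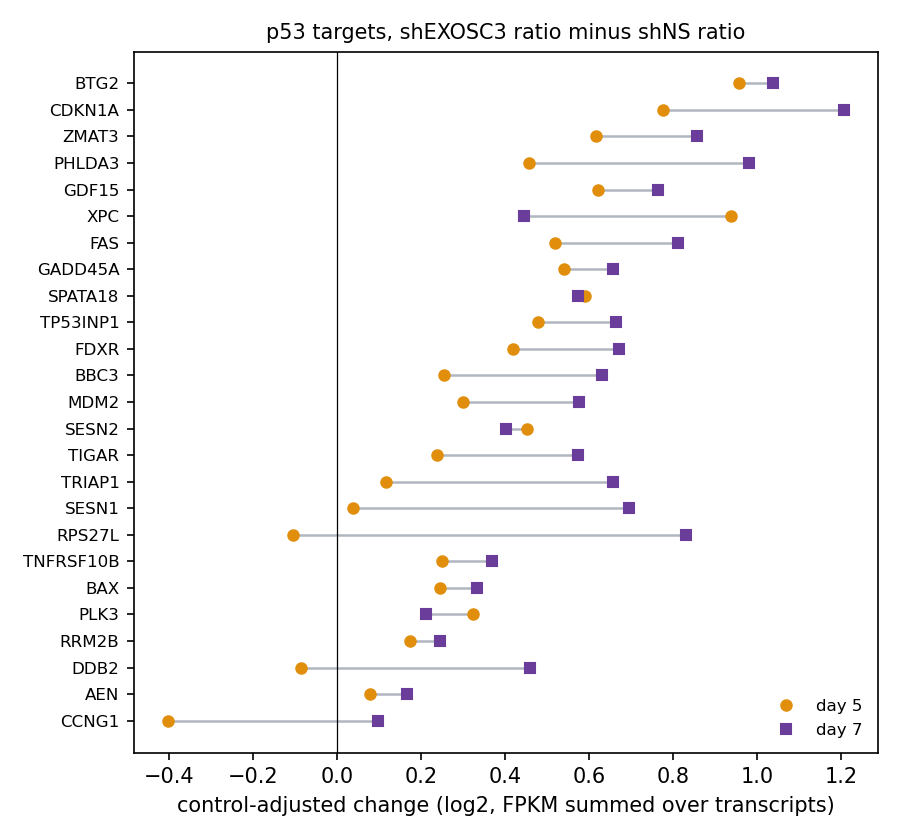
Adjusted log2 difference of each of the 25 measured p53 targets on day 5 and day 7, named control-adjusted change on the axis, with FPKM summed over transcripts; each point is 1 gene on 1 day and a line joins the days. Of the 25 genes, 22 lie above 0 on both days and the medians are 0.32 and 0.63.

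Pluripotency and lineage genes bear on the differentiation named in the series title. The 24 pluripotency genes had median adjusted log2 differences of -0.07 and -0.10, within the central 95% of random lists on both days, at percentiles 73.0 and 14.6. On both days, 3 lay above 0 and 10 below 0. SOX2, a core pluripotency factor, went from 253 to 172 FPKM on day 5 and from 253 to 175 FPKM on day 7 in shEXOSC3, and from 214 to 184 and 262 to 234 FPKM in shNS, an adjusted log2 difference of -0.34 and -0.37. POU5F1 had -0.10 and 0.17, NANOG 0.27 and -0.04, MYCN -0.62 and -0.24, or -0.28 and -0.24 summed, and PODXL 0.63 and -0.10. With doxycycline the list's median was lower in both lines, at -0.20 and -0.30 in shEXOSC3 and -0.24 and -0.25 in shNS, and 13 of the 24 genes lay below 0 in all 4 tables. These medians lay at percentiles 2.67 and 0.18 in shEXOSC3 and at 0 and 0.02 in shNS. Limma called 0 of the 24, over all genes or adjusted over the list alone, with 2 at an unadjusted p under 0.05.

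Few lineage genes reached a mean of 1 FPKM. In the mesendoderm and primitive streak list 3 of 20 did: FOXH1, a nodal pathway transcription factor, had 0.71 and 0.46, the ligand NODAL 0.17 and 1.14, and WNT3 0.11 and 0.32, and the list's medians lay at percentiles 67.3 and 91.6. FOXH1 (hg19, chromosome 8, 145691720 to 145701718) went from 15.0 to 23.2 and from 6.18 to 7.54 FPKM in shEXOSC3, against 16.2 to 14.8 and 6.12 to 5.17 FPKM in shNS. Definitive endoderm genes (5 of 18 measured) had medians of -0.14 and 0.28, with CLDN6 at -0.02 and 0.52, AFP at -0.14 and 0.32, KIT at -3.35 and -0.34, or 0.10 and -0.34 summed, and APOA1 at 0.28 and -0.85. Mesoderm genes (5 of 22) had -0.01 and -0.05, with BMP4 at 1.77 and -0.05, or 0.26 and -0.10 summed, COL1A1 at 1.25 and -0.07, PDGFRA at -0.34 and -0.26 and MSX2 at -0.41 and -0.04. Among neuroectoderm genes (3 of 22, medians 0.27 and -0.23), FABP7, a fatty acid binding protein of neural progenitors, was lower, from 13.0 to 3.60 and from 9.29 to 3.89 FPKM in shEXOSC3 against 10.8 to 7.76 and 8.85 to 7.67 FPKM in shNS. With transcripts summed, FABP7 passed limma's test adjusted over the list alone (adjusted p 0.0239) and 0 members passed over all genes. OTX2 had 0.27 and 0.04 and NES 0.29 and -0.23. Trophectoderm and amnion genes (4 of 20) had medians of 0.07 and 0.10, with TFAP2C at 0.14 and 0.36 and IGFBP3 at -0.17 and -0.28. Fibroblast and stromal genes (11 of 16), a check for other cell types, had 0.19 and 0.11, at percentiles 96.8 and 86.1, with ACTA2 at 0.56 and 1.37, or 0.14 and 0.63 summed, and S100A4 at -0.22 and -0.37. With doxycycline the medians of this list were 0.38 and 0.16 in shEXOSC3, at percentiles 99.98 and 95.8, and 0.19 and -0.06 in shNS, at percentiles 99.1 and 33.8. On dominant transcripts limma called 0 lineage genes, over all genes or adjusted over each list alone, and FOXH1, FABP7 and ACTA2 had an unadjusted p under 0.05.

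Signalling, growth and housekeeping lists were compared in the same way. Ribosome biogenesis genes (26 of 26) had -0.11 on day 5 and -0.19 on day 7, at percentiles 49.6 and 0.67; the nucleolar protein NPM1 had -0.39 and -0.88 and NIP7 -2.66 and -0.56, against 0.61 and 0.45 for NOP14 and 2.81 and -0.49 for GNL3. Summed over transcripts these became -0.25 and -0.15 for NIP7, -0.05 and 0.18 for NOP14 and -0.36 and -0.46 for GNL3. Cell cycle genes (24 of 24) had -0.11 and -0.19, at percentiles 59.6 and 1.06, with 16 below 0 on both days, CDK1 at -0.26 and -0.49, AURKA at -0.50 and -0.59, or -0.26 and 0.13 summed, and PLK1 at 0.75 and 0.05. Nodal and TGF-beta targets (12 of 16) had -0.01 and -0.11, with ID2 at -0.35 and -0.57 and SMAD7 at 0.16 and -1.40, or 0.26 and 0.13 summed. WNT targets (5 of 16) had 0.15 and -0.05, with ZNRF3 at 1.46 and 0.14, or 0.32 and 0.27 summed, and AXIN2 at -0.10 and -0.26. Retinoic acid targets and HOX genes (3 of 15) had -0.25 on both days, with CYP26A1 at -0.25 and -0.65 and DHRS3 at 0.11 and 0.13. Interferon response genes (5 of 20) had 0.33 and 0.27, at percentiles 97.1 and 93.0, or 0.09 and 0.07 over 7 genes summed, at percentiles 72.5 and 73.2, with BST2 at 0.36 on both days and IFI6 at 1.02 and 0.27, or 0.37 and -0.10 summed. Genes of mitochondrial translation and respiratory complex I (17 of 17) had -0.19 and 0.05, with NDUFB3 at -1.64 and 0.01, or -0.54 and 0.03 summed, and MRPL12 at 0.90 and -0.17. The 62 replication-dependent histone genes had -0.44 and 0.10 and the 80 ribosomal protein genes -0.31 and 0.03; both lay below all random lists on day 5 and above the central 95% on day 7, at percentiles 99.93 and 97.8, where the histone median was -0.051 and the ribosomal protein median -0.13 in shEXOSC3 without subtraction. The 370 ZNF genes had 0.01 and -0.01. No member of these lists passed limma's test, over all genes or adjusted over the list alone; at an unadjusted p under 0.05 there were 3 of ribosome biogenesis, 1 of the cell cycle, 4 of the nodal and TGF-beta targets, 1 of the interferon response, 4 histones, 4 ribosomal proteins and 9 ZNF genes.

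Differences shared by both lines with doxycycline were examined in shNS, which carries no hairpin against EXOSC3. Genes of the integrated stress and unfolded protein response, induced by amino acid shortage or misfolded protein, were higher in all 4 tables, with medians of 0.55 and 0.41 in shEXOSC3 and 0.43 and 0.35 in shNS, each above all 10000 random lists. Of the 20 genes, 11 lay above 0 in all 4 tables and 1 below. SESN2 went from 15.0 to 27.9 and from 13.7 to 27.0 FPKM in shEXOSC3 and from 16.2 to 21.7 and from 13.6 to 20.1 FPKM in shNS. The serine synthesis enzyme PSAT1 had log2 ratios of 0.99 and 0.69 in shEXOSC3 and 0.29 and 0.32 in shNS, and the transcription factor ATF3 of -0.05 and 0.25 and of 0.62 and 0.28. After subtraction of shNS the list's medians were 0.09, at percentile 98.7, and 0.01, at percentile 72.0, with 0 genes called by limma and 2 at an unadjusted p under 0.05.

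The 5 largest shNS ratios of the same direction on both days were single transcripts of PLEKHB2 (3.62 and 4.20), C21orf91 (3.17 and 4.53), TEAD2 (4.05 and 3.13), EIF2B4 (3.14 and 2.93) and UNC5B (2.72 and 2.78), all of genes with several transcripts. With transcripts summed, 4 named genes at loci of at least 300 bp were at least 2-fold apart in shNS on both days, and are given although chosen after their values were seen. VIM, which encodes the intermediate filament vimentin (hg19, chromosome 10, 17256238 to 17279592), went from 79.9 to 352 and from 82.9 to 244 FPKM in shNS and from 88.8 to 524 and from 87.7 to 431 FPKM in shEXOSC3. TRIB3, a pseudokinase of the stress response, had log2 ratios of 1.36 and 1.16 in shNS and 1.53 and 1.24 in shEXOSC3. DPPA5, a gene of pluripotent cells, had -1.20 and -1.11 in shNS and -1.78 and -1.08 in shEXOSC3, and XCL2 had 1.130 and 1.101 in shNS. No library separates doxycycline from the expression of a hairpin.

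The day-averaged comparison asked for effects of the knockdown common to both days. Limma, with the 2 days of a line as its observations and 2 residual degrees of freedom, called 0 of 12965 genes at an adjusted p of 0.05; 548 genes, or 4.23%, had an unadjusted p under 0.05. In simulated data, the same test recovered 0% of 100 genes moved by 3 on the log2 scale, so a count of 0 says little here. Summed over transcripts it also called 0 of 13387 genes, with 780 at an unadjusted p under 0.05. In simulated summed data the test recovered 82% of genes moved by 3 and 15% of those moved by 1.5. This count of 0 may therefore say more, but only about large effects. The simulation shuffled shNS ratios among genes of like expression and did not keep each gene's own spread. Its recovery rates may thus not hold for the genes here. Without the trend on expression, the summed values gave 2 calls by limma, the microRNA genes MIR330 and MIR940, both lower and chosen after their values were seen. Both were listed at 23.6 and 0 FPKM on day 5 and at 19.8 and 0 FPKM on day 7 in shEXOSC3 and at 0 in shNS, the same to 3 digits for both genes. In those libraries MIR940 shared the lowest value above 0 at loci of its length with 3 other transcripts, so its value can rest on 1 read. The read number behind MIR330, which lies in a longer locus with other transcripts, is unknown. Among the 335 microRNA genes, limma called 2 adjusted over the list alone on dominant transcripts and 5 on summed values.

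Agreement between the days was weak across genes. Across 12965 genes, the shEXOSC3 log2 ratios of day 5 and day 7 had a Pearson r of 0.08 and a Spearman rho of 0.31, against 0.04 and 0.08 in shNS; genes are not independent replicates, so no p-value is given. Across 8601 genes with a mean of at least 5 FPKM, summed over transcripts and without short RNAs, the values were 0.46 and 0.48 in shEXOSC3 and 0.17 and 0.13 in shNS. They were 0.27 and 0.30 for shEXOSC3 on day 5 against shNS on day 7, and 0.20 and 0.18 for shEXOSC3 on day 7 against shNS on day 5. Between the lines on the same day they were 0.31 and 0.19 on day 5 and 0.23 and 0.38 on day 7. Part of the agreement in shEXOSC3 is thus shared with shNS. For the adjusted log2 differences the values were 0.18 and 0.18. The adjusted log2 difference was at least 1 higher on day 7 than on day 5 for 1008 genes and at least 1 lower for 1121. The 5 highest by this measure were the DNA repair enzyme APEX1 (-0.08 on day 5 and 14.2 on day 7), prothymosin PTMA (-0.57 and 11.98), PLIN3 (-5.23 and 5.33), the ribosomal protein gene RPL11 (-9.25 and -0.14) and TTC1 (-2.08 and 6.18). The 5 lowest were NIT1 (6.75 and -1.96), IST1 (0.41 and -7.72), ANKHD1 (1.34 and -5.64), the antizyme OAZ2 (0.37 and -6.54) and POLR3E (1.42 and -5.19). All 10 have several transcripts; after summing, APEX1 stood at 0.20 and -0.15 and OAZ2 at 0.31 and -0.32, and the 2 counts became 399 and 426.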

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

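The 2 lists and 5 genes below were picked out because their adjusted log2 differences had opposite signs on day 5 and day 7; with 1 library per group, none of these differences between days was tested. Of the tests in this part, the rates by number of transcripts and by expression were fixed before their results were seen, and the comparison of the rates in shEXOSC3 and shNS was chosen only after.

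Replication-dependent histone genes had a median of -0.44 on day 5 and 0.096 on day 7 over 62 genes. Their shEXOSC3 medians were -0.27 and -0.05 and their shNS medians 0.18 and -0.12, so the day 5 value came from both lines. Ribosomal protein genes had -0.31 and 0.030 over 80 genes, with shEXOSC3 medians of -0.18 and -0.13 and shNS medians of 0.12 and -0.18.

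PLIN3, a lipid droplet protein, had -5.23 on day 5 and 5.33 on day 7, and -0.06 and 0.22 with its transcripts summed. For TTC1 the values were -2.08 and 6.18, and -0.27 and -0.22 summed. NIT1 had 6.75 and -1.96, and 0.14 and 0.10 summed. ANKHD1 had 1.34 and -5.64, and -0.03 and -0.18 summed. POLR3E, a subunit of RNA polymerase III, had 1.42 and -5.19, and -0.13 and 0.06 summed.

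Large values of single transcripts, as in these 5 genes, form the first pattern that was weighed. Among loci of at least 300 bp outside short RNA classes, genes with 1 transcript passed the adjusted size rule on day 7 at 0.115 times the rate of genes with several (bootstrap interval 0.0906 to 0.139), which is consistent with a division of reads among the transcripts of a gene that differs between libraries. Counting noise of low values was argued against as the whole cause, since genes at 1 to 5 FPKM passed at 1.60 times the rate of those at 5 or more (1.41 to 1.79), below the 3 times set in advance. Among genes with 1 transcript, however, 3.33% passed at 1 to 5 FPKM and 0.931% at 5 or more, so counting noise stays open as a part of the cause. For a switch of transcripts by the knockdown, the rate in genes with several transcripts was compared between the lines. On day 7 it was 0.953 times the shNS rate in shEXOSC3 (0.871 to 1.04), below the 1.5 times asked for on both days. On day 5 that ratio was 1.91 (1.65 to 2.20), in tables whose shNS libraries differ more in depth. The shNS rate itself was 3.75% on day 5 and 9.95% on day 7, without a knockdown. With 1 library per group, none of these intervals measures spread between libraries. The ratios therefore cannot decide, and a switch stays open on both days.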

How the results depend on the processing

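Summing FPKM over transcripts, genes with 1 transcript only, and limma without trend on summed values were chosen after the data were seen; all other alternatives were planned. Of 154 alternative values of counts and agreement, 74 stayed, 80 moved and 0 changed direction. A count stayed if it lay within 1.5 times the main count or equalled it, as with 0 limma calls. A correlation stayed if it lay within 0.05 of the main value. Of 594 list medians, 490 stayed within their spread, 96 moved and 8 of those outside the central 95% of random lists changed sign. Of 1392 values of named genes, 1059 stayed, 266 moved and 67 of those past the size rule changed sign. Centring, no minimum FPKM, transcripts with a successful test only and loci of at least 300 bp moved no count by over 1.5 times. Limma called 0 genes under each of the other alternatives, with 363 to 1097 genes at an unadjusted p under 0.05, and without each ratio in turn, where the lone ratio of a line is assumed to vary like the other line's, it also called 0; on summed values without trend it called 2. Scaling by spike-ins was not run, as the tables hold 0 spike-in entries. Pairing the lines by day left 0 calls and 446 genes at an unadjusted p under 0.05. Total depth is unknown, which limits every value of low genes. The cause was not tested for any value below unless stated.

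With a pseudocount of 0.1 FPKM, 582 genes were higher in shEXOSC3 on day 5 and 798 higher and 690 lower on day 7, 337 were higher and 299 lower in shNS on day 5, 137 were higher and 126 lower by the adjusted difference on both days, and 57 and 43 in shNS on both days. With 5 FPKM, these counts were 161 higher and 124 lower in shEXOSC3 on day 5, 246 and 200 on day 7, 109 and 91 in shNS on day 5, 243 and 189 on day 7, 24 and 26 by the adjusted difference on both days, and 20 and 9 in shNS on both days. A larger pseudocount shrinks the ratios of low genes by construction.

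At a minimum mean of 5 FPKM, where fewer genes were analysed, shEXOSC3 had 215 higher and 181 lower on day 5 and 311 and 267 on day 7, shNS 110 and 101 on day 5 and 306 and 246 on day 7, the adjusted difference 44 and 40 on both days, shNS 23 and 17 on both days, and day 7 against day 5 604 and 628. A fold of 1.5, a lower threshold, gave 947 and 780 in shEXOSC3 on day 5 and 1134 and 974 on day 7, 478 and 458 in shNS on day 5 and 882 and 800 on day 7, 244 and 199 by the adjusted difference on both days, and 99 and 82 in shNS on both days.

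Summed over transcripts, shEXOSC3 had 183 higher and 108 lower on day 5 and 265 and 156 on day 7, shNS 100 and 84 on day 5 and 177 and 124 on day 7, the adjusted difference 41 and 25 on both days, shNS 19 and 11 on both days, and day 7 against day 5 399 and 426. Of 139 symbols past the adjusted rule on both days by dominant transcript and 57 by the sum, 53 were shared. In genes with 1 transcript, 6784 genes, the same counts were 154 and 91, 226 and 144, 92 and 79, 169 and 118, 36 and 25, 18 and 11, and 345 and 382. Without subtraction of shNS, 41 genes were higher and 36 lower on both days, and with doxycycline libraries compared across tables the counts were 39 and 30.

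List medians changed sign for exosome subunits on day 7, at -0.14 summed and -0.057 across tables. They also did so for histones on day 7, at -0.051 in shEXOSC3 alone and -0.066 across tables, and for ribosomal proteins on day 7, at -0.13 in shEXOSC3 alone. Across tables, snoRNA hosts (-0.019), H/ACA box snoRNAs (-0.67) and Cajal body RNAs (-0.39) changed sign on day 5.

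Other list medians moved by more than the spread of random lists. In shEXOSC3 alone on day 5 they were -0.078 for exosome subunits, -0.057 for exosome cofactors, -0.20 for pluripotency, 0.095 for definitive endoderm, -0.48 for neuroectoderm, 0.38 for fibroblast and stromal genes, 0.12 for p53 targets, 0.55 for the stress response, -0.021 for the cell cycle, -0.59 for retinoic acid targets, -0.063 for mitochondrial translation and complex I, 0.21 for H/ACA box snoRNAs, 0.22 for LINC genes, -0.27 for histones and -0.18 for ribosomal proteins. On day 7 they were 0.056 for exosome subunits, 0.014 for cofactors, -0.30 for pluripotency, -0.20 for endoderm, -0.31 for mesoderm, -0.089 for snoRNA hosts, 0.37 for p53 targets, 0.41 for the stress response, -0.47 for ribosome biogenesis, -0.16 for mitochondrial translation and complex I, 0 for C/D box and 0.28 for H/ACA box snoRNAs, 0.27 for LINC genes, 0.34 for antisense RNAs and -0.041 for ZNF genes.

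Across tables, day 5 medians moved to -0.33 for neuroectoderm, 0.35 for p53 targets, -0.85 for snRNAs, -0.026 for microRNA hosts, 0.17 for antisense RNAs, -0.30 for histones and -0.17 for ribosomal proteins. Day 7 medians moved to 0.022 for cofactors, -0.28 for endoderm, 0.28 for mesoderm, 0.18 for snoRNA hosts, 0.77 for p53 targets, 0.21 for nodal and TGF-beta targets, 0.50 for WNT targets, 0 for C/D box and 0.29 for H/ACA box snoRNAs, 0.046 for Cajal body RNAs and 0.033 for ZNF genes. Summed over transcripts they moved to 0.32 for p53 targets, 0.086 for the interferon response and -0.016 for ZNF genes on day 5 and to 0.046 for cofactors on day 7.

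With a minimum of 5 FPKM, which removes members, the day 5 medians moved to -0.11 for cofactors, 1.25 for mesoderm, 0.021 for snoRNA hosts, -0.13 for nodal and TGF-beta targets, 0.095 for LINC genes, 0.081 for antisense RNAs and -0.047 for ZNF genes, and the day 7 medians to 0.026 for cofactors, 0.062 for the interferon response, -0.28 for C/D box snoRNAs, -0.11 for microRNA hosts and 0.47 for antisense RNAs. With no minimum they moved on day 5 to 0.029 for the interferon response, 0.025 for microRNA hosts, 0 for LINC genes and 0.039 for antisense RNAs, and on day 7 to 0.017 for endoderm, 0.055 for the interferon response, 0.045 for nodal and TGF-beta targets, -0.019 for microRNA hosts, 0.00058 for LINC genes, 0.032 for antisense RNAs and 0.044 for histones. With successfully tested transcripts only, they were 0.017 for cofactors, 0.78 for WNT targets, 0.48 for C/D box snoRNAs and 0.22 for microRNA genes on day 5, and -0.031 for endoderm, -0.44 for C/D box snoRNAs, 0.10 for microRNA genes and -0.11 for microRNA hosts on day 7. A pseudocount of 5 FPKM gave 0.16 for p53 targets, 0.077 for microRNA hosts, 0.092 for LINC genes and 0.091 for antisense RNAs on day 5 and 0.48, 0.12, 0.19 and 0.13 on day 7. A pseudocount of 0.1 FPKM gave -0.16 for nodal and TGF-beta targets, 0.46 for WNT targets and 0.33 for antisense RNAs on day 5 and 0.39 for antisense RNAs on day 7. At loci of at least 300 bp, C/D box snoRNAs had -0.052 on day 7.

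Among values of single genes past the size rule, these changed sign. Summed over transcripts on day 5: C7orf25 -0.044, PRKG2 -0.15, DHX35 -0.15, C21orf91 0.30, MAD1L1 0.033, ING4 0.15, EIF2B4 0.52, UXS1 0.13, ZNF180 0.069, POLG 0.0014, ANKHD1 -0.030, POLR3E -0.13, UNC5B 0.43, KIT 0.10, GADD45A 0.54, TRIB3 0.16 and GNL3 -0.36. On day 7: DMAP1 -0.19, TNNT2 -1.36, ING4 0.43, PLEKHB2 0.094, CTSL 0.0060, ZNF180 0.10, APEX1 -0.15, PTMA -0.24, TTC1 -0.22, NIT1 0.10, IST1 0.072, POLR3E 0.056, FDXR 0.67 and SMAD7 0.13. In shEXOSC3 alone on day 5: C7orf25 -0.077, C21orf91 1.49, MAD1L1 0.30, PLEKHB2 0.061, ANKHD1 -0.62, UNC5B 0.49 and TRIB3 1.94. On day 7: NUMB -0.039, DMAP1 -0.044, PLEKHB2 0.030, EIF2B4 0.19, UXS1 0.23, NIT1 0.25, UNC5B 0.46 and SMAD7 0.52. With doxycycline libraries across tables on day 5: TEAD2 1.75, C21orf91 0.47, MAD1L1 0.18, EIF2B4 0.11, CTSL 0.11, PLIN3 0.033, POLR3E -0.069, UNC5B 0.39, GADD45A 0.97, TRIB3 0.22 and GNL3 -1.05. On day 7: SAFB -0.033, SDCBP -0.00039, TNNT2 -0.47, PLEKHB2 0.41, EIF2B4 0.21, UXS1 0.63, TTC1 -0.27, NIT1 0.11, UNC5B 0.045 and SMAD7 0.68.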

Other observations

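Of the tests in this part, those of antisense against sense genes and of long noncoding RNAs outside the lists were fixed before their results were seen, and the other tests were chosen only after.

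Several short RNAs differed between the days in both lines and with or without doxycycline. RMRP, the RNA of RNase MRP, stood at 87126 to 115224 FPKM in the 4 day 5 libraries and at 11204 to 15033 FPKM in the 4 day 7 libraries. RPPH1, the RNA of RNase P, stood at 62970 to 73648 and at 2320 to 2810 FPKM, and the snoRNA SNORA73B at 12137 to 23373 and at 2540 to 2742 FPKM. MIR302C, of a microRNA cluster abundant in pluripotent cells, was listed at 0 on day 5 and at 12212 to 17241 FPKM on day 7. SNORD116-13 stood at 52.7 to 165 and at 9312 to 19678 FPKM, and MIR198 at 0 and at 10704 to 14496 FPKM. These genes were chosen after their values were seen. The libraries of a day may also share a preparation, and the tables of the days were made separately, so day and preparation cannot be separated.

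Long noncoding RNAs outside the lists, 190 genes named neither as LINC nor as antisense, had median adjusted log2 differences of 0.22 on day 5 and 0.20 on day 7, above all 10000 random lists on both days. Their shEXOSC3 medians were 0.18 and 0.21 and their shNS medians -0.04 and -0.06. Over all 506 long noncoding RNAs the medians were 0.21 and 0.25, and over 11334 protein-coding genes -0.02 on both days.

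The second pattern weighed was the higher level of antisense and intergenic RNAs in shEXOSC3 with doxycycline. For the antisense RNAs, the smaller median of antisense minus sense over 178 pairs was 0.242 (bootstrap interval 0.0613 to 0.381). This argues against reads of the listed sense transcripts, which would move both genes of a pair alike. Sense reads outside the listed transcripts were not measured, and the counting strand is not given. Reads of an overlapping sense gene therefore stay open for the antisense RNAs. Reads of an overlapping gene were argued against as the whole cause for the intergenic RNAs on day 7. There, 67 LINC genes whose locus overlaps no other gene had a median of 0.413, against -0.0918 to 0.120 in random lists. On day 5 that median was 0.162, within -0.0383 to 0.169, although in shEXOSC3 alone it was 0.199, above -0.0275 to 0.157, and the median of 17 LINC genes with an overlap was higher by 0.174 (bootstrap interval -0.211 to 0.418), so for the intergenic RNAs this explanation stays open on that day. A difference in depth would move both classes most in the shNS tables, whose libraries differ most in depth. The median of both classes lay further from 0 in shEXOSC3, by 0.164 (bootstrap interval 0.0860 to 0.223) on day 5 and by more on day 7. That difference is part of the pattern itself and so is no separate test. The depth ratios, 1.01 and 0.922 in shEXOSC3 against 1.59 and 1.33 in shNS, argue against depth as the whole cause. They are estimates: in shNS on day 5 the ratio rests on 504 of 10689 low values. The class outside the lists gave 0.204 as its smaller median, which is consistent with a hypothesis that loss of exosome activity raises long noncoding RNAs as a class, although overlap with other genes was not examined in that class. With 1 library per group and 1 hairpin, effects of the hairpin sequence beyond EXOSC3 stay open.

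The third pattern was the higher level of stress response genes with doxycycline in both lines. A difference in depth was argued against as the whole cause, since the list was higher in all 4 tables while the depth of the doxycycline library was 0.922 times that of its partner in shEXOSC3 on day 7 and 1.59 and 1.33 times in shNS, so depth went both ways. The smaller shNS median, 0.353, is part of the pattern itself and so tests no explanation. Doxycycline, expression of any hairpin and differences in culture between the dishes cannot be told apart by these libraries.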
